A study of Mus musculus with 8 samples.

How the data were processed

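RNA of perigonadal white adipose tissue from 8 male mice was isolated with a phenol and column method, amplified, and hybridised to Affymetrix HT MG-430 PM arrays, with 1 array per mouse. The values used were the authors' deposited log2 expression values, 1 per probe set and array. Per the submitters' processing notes they were made with RMA in the affy package, whose version is not given in the sources used here. RMA corrects background, normalises quantiles between arrays and summarises probes, so shifts shared by all transcripts are removed, and differences of weakly hybridised probe sets are compressed. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed.

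The deposited table held 45141 probe sets, of which 104 were controls. The platform annotation listed 28898 probe sets with 1 gene symbol, 551 with several and left 15692 unlisted. Those with several or no symbol were not named. Symbols were updated through the Entrez identifier in the RefSeq table of GRCm38.p6, which held 28689 of the 28898. For each gene the probe set with the highest mean over all 8 arrays stood for the gene, which left 17097 genes. The background bound was the 95th percentile of 23 nonspecific control probe sets over all arrays, 6.94 log2 units. It was used to describe readings, not to filter them.

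Genotype and litter were taken from the labels, which name each mouse separately. Replicate numbers were given in accession order and pair nothing. KO was compared with LoxP in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, Benjamini-Hochberg adjustment over genes, threshold 0.05). Gene lists were tested with camera at its preset correlation of 0.01, two-sided, adjusted over 33 lists, with an estimated correlation beside it and with fry. The lists were fixed with 986 entries, of which 870 were measured. Where a list is described "adjusted over the list alone", the adjustment was over its measured members. Single values were tested with a two-sided exact permutation test over the 70 relabellings of the 8 arrays, whose smallest p is 0.0286. List means per array were tested the same way, a test added after the data were examined. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

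Named genes followed a rule written before the data were examined, as were the gene lists, the comparison of genotypes and most alternatives. The rule took Trp53inp2 and Trp53inp1, then genes past adjusted p 0.05 with non-overlapping groups (up to 12 per direction). Where fewer passed, it filled up to 10 per direction with the smallest unadjusted p among genes with non-overlapping groups and a log2 difference of at least 0.58 in size. From each list described it took up to 4 members, those past the adjusted threshold by size and then those with the smallest unadjusted p.

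Alternatives were litter as a fixed or random block, each litter alone, rescaling of the arrays, filters on dim genes, other choices among probe sets, other variance models, array weights, an ordinary test with pooled variance, a looser threshold, and leaving out each array. Within a litter only 1 LoxP array was present, so the spread was pooled over all arrays and the lone array was assumed to vary like the others. With KO 4 alone the spread came from the LoxP arrays, and KO 4 was assumed to vary like them. Leaving out KO 1 and KO 2, leaving out KO 1, KO 2 and LoxP 4, comparing KO 4 alone, and the epididymis list mean as a covariate were added after the data were examined.

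The procedure was tested on simulated data made from the means and spreads of the 17097 genes of the KO and LoxP comparison, with 200 genes changed in each of 10 runs. It recovered 82.7% of genes changed by 1 log2 unit and 95.7% of those changed by 2, with 4.70% of the calls false and a mean of 0 calls when nothing was changed. A list shifted by 0.3 was called in 10 of 10 runs with either correlation, and a mean of 0.1 lists per run was called when nothing was changed. Simulated genes varied independently, unlike genes in tissue.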

Results

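Transcript levels were measured on 8 arrays, each hybridised with RNA from the perigonadal white adipose tissue of 1 male C57BL/6J mouse. This depot is the fat pad beside the epididymis. In the 4 KO mice both Tp53inp2 alleles were flanked by loxP sites and a ubiquitously expressed, tamoxifen-inducible Cre recombinase was present. The 4 LoxP control mice carried the same alleles without Cre. All mice received a tamoxifen diet from 2 months of age and were sampled at 4 months, so genotype and the presence of active Cre differed together. The mice came from 3 litters. Litter Cx28 held 2 KO mice and 1 LoxP mouse, litter Cx34 likewise held 2 KO mice and 1 LoxP mouse, and litter Cx33 held 2 LoxP mice. Array medians lay between 6.17 and 6.21 log2 units, and the number of arrays limits the precision of all that follows.

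To determine whether the target transcript was lost, Trp53inp2, read by 1 probe set, was examined first. TP53INP2 is a nuclear and cytosolic protein that takes part in autophagosome formation. Its transcript was lower on all 4 KO arrays than on any LoxP array, with 10.57 ± 0.65 log2 units (SD, n = 4) in KO and 11.94 ± 0.15 (SD, n = 4) in LoxP. The log2 difference was -1.38 ± 0.30 (SE), which is 2.60-fold lower in KO. The two-sided exact permutation p was 0.0286, the smallest that 70 relabellings of the arrays can give, while the limma adjusted p over all genes was 0.479. KO 2 was lowest at 9.62, and the other KO arrays read 10.71, 11.05 and 10.88. All of these lay above the background bound of 6.94, so the transcript was lowered but still read. Without KO 1 and KO 2 the log2 difference was -0.97 ± 0.11 (SE). Within litter Cx28 the log2 difference was -0.76, within litter Cx34 it was -1.81, and with litter as a block it was -1.29. The labels do not say which exons were removed, and a probe outside them would not report the deletion. The paralogue Trp53inp1 gave a log2 difference of 0.07 ± 0.15 (SE, adjusted p = 0.912).

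**Figure D1:**
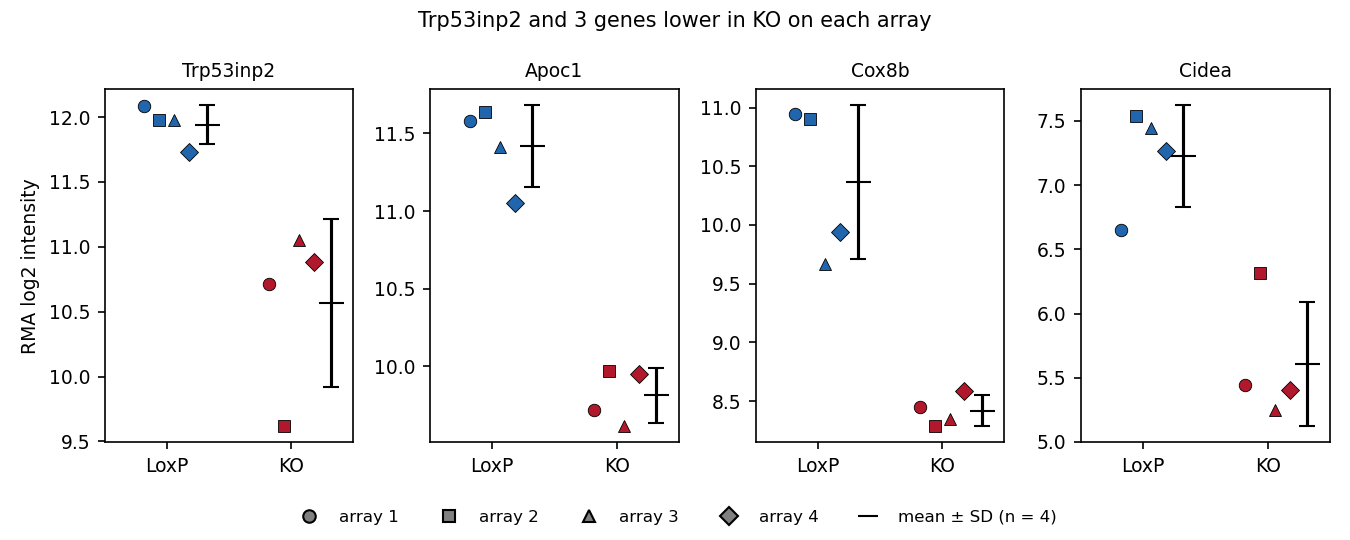
RMA log2 intensity (y axis) of Trp53inp2, Apoc1, Cox8b and Cidea on each of the 4 LoxP (blue) and 4 KO (red) arrays, with the mean ± SD of each group as black bars. Marker shapes name arrays 1 to 4 of a group and do not pair arrays between groups. In each panel all 4 KO arrays lie below all 4 LoxP arrays, and the y axes do not start at 0.

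The comparison of KO with LoxP tissue then asked which other transcripts differ after the Tp53inp2 deletion is induced in adult mice. The naming rule took 10 genes with lower and 10 with higher readings in KO. Cox8b, a subunit of cytochrome c oxidase that is abundant in brown and beige fat, read 8.42 ± 0.13 (SD, n = 4) in KO and 10.36 ± 0.66 (SD, n = 4) in LoxP, 3.86-fold lower. Apoc1, an apolipoprotein of triglyceride-rich particles, read 9.81 ± 0.18 in KO and 11.42 ± 0.26 in LoxP, with a log2 difference of -1.61 ± 0.14 (SE). Arxes1, an adipocyte-related X-linked gene, differed by -1.59 on the log2 scale, Aldh3b2 by -1.10 and Mogat1, which makes diacylglycerol from monoacylglycerol, by -0.96. Tmem45b (-1.01), Tmem53 (-0.96), Trpv1 (-0.88), Aatk (-0.60) and the RIKEN-named transcript 4931406C07Rik (-0.59) completed the 10 lower genes. None of these passed the test: of 17097 genes, limma called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.0871, for Apoc1. Apoc1 gave a log2 difference of -1.27 within litter Cx28, -1.57 within litter Cx34 and -1.42 with litter as a block, and its adjusted p was under 0.05 in 5 of 29 alternative analyses. The means of Trpv1 in both groups, and of Arxes1 and Aatk in KO, lay under the background bound of 6.94.

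Among the 10 genes with higher readings in KO, Hspb7, a small heat shock protein of muscle, read 9.40 ± 0.67 (SD, n = 4) in KO and 7.88 ± 0.46 (SD, n = 4) in LoxP. Trp63, a transcription factor of basal epithelial cells, read 8.08 ± 0.56 in KO and 6.59 ± 0.25 in LoxP, and its 4 probe sets gave log2 differences from 0.07 to 1.48. Lama3, a chain of epithelial basement membrane laminin, differed by 0.79, the tyrosine kinase Src by 0.74, Cpm by 0.71, the hexokinase Hk1 by 0.70, and Reep1 and Arhgap11a by 0.66 each. Glb1, the lysosomal beta-galactosidase, and Plekha1 each differed by 0.59. Adjusted p for these 10 genes ran from 0.353 to 0.638, so none passed. The rule required all KO readings above all LoxP readings, so the highest of the 8 had to lie on 1 of the 4 KO arrays. For 9 of the 10 it lay on KO 1 or KO 2. The median log2 difference of the set was 0.71 with all arrays and 0.46 without KO 1 and KO 2. Hspb7 went the other way, from 1.52 with all arrays to 2.08 without those arrays. Reep1 likewise went from 0.66 to 0.72, while the rest of the set had smaller differences. Among the 10 lower genes, KO 1 or KO 2 held the lowest reading for 6. Their median was -0.99 with all arrays and -1.04 without KO 1 and KO 2. Cpm and Lama3 lay under the background bound in both groups, Trp63 and Arhgap11a did so in LoxP, and single probe sets gave only 0.02 for Lama3 and 0.04 for Plekha1.

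**Figure D2:**
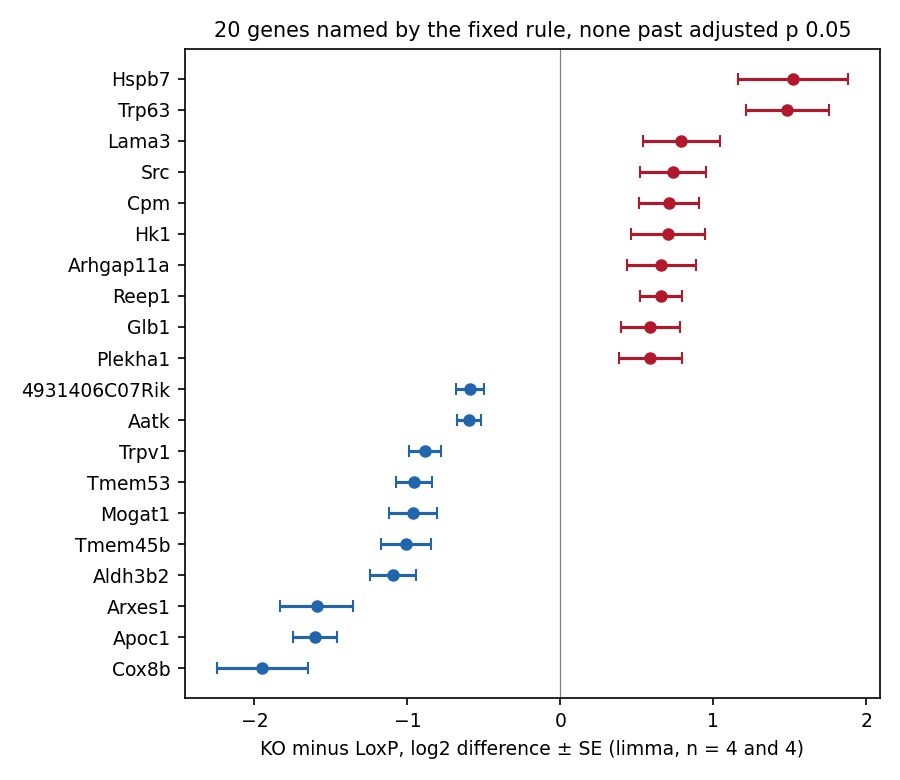
KO minus LoxP log2 difference with its standard error (x axis, limma, 4 KO and 4 LoxP arrays) for the 20 genes taken by the naming rule (y axis). Red marks higher and blue marks lower readings in KO, and none passed an adjusted p of 0.05.

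Over all genes, 1250 had an unadjusted limma p under 0.05, of which 501 were higher and 749 lower in KO, where chance alone would give about 855. Without LoxP 2 the count was 776, and 5 of the 35 splits of the arrays into 4 and 4, counting the real one, gave as many as 1250. The ordinary test with pooled variance gave 1100 such genes and likewise 0 after adjustment. In 835 genes (4.88%) the 4 KO and 4 LoxP readings did not overlap, against 2.86% expected by chance, and 481 of these were lower in KO. With litter as a block, 878 genes had an unadjusted p under 0.05 and 0 passed the adjusted threshold.

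Genes of fatty acid oxidation were lower together in KO. All 24 measured members of this fixed list had a negative log2 difference, with a median of -0.37 (camera adjusted p = 1.24e-15 with the preset correlation, and adjusted p = 0.547 with an estimated correlation). Adjusted over the list alone 16 members fell and 0 rose, while adjusted over all genes 0 passed. Acaa1b, a peroxisomal thiolase, fell by 1.03 on the log2 scale, the medium-chain and long-chain acyl-CoA dehydrogenases Acadm and Acadl fell by 0.54 and 0.58, and the mitochondrial thiolase Acaa2 fell by 0.44. The other Acadl probe set gave -0.02. The list mean was 9.81 ± 0.17 log2 units (SD, n = 4) in KO and 10.20 ± 0.15 (SD, n = 4) in LoxP, a difference with an exact permutation p of 0.0571 (adjusted p = 0.314 over 33 lists). Its median was -0.49 within litter Cx34, -0.04 within litter Cx28 (adjusted p = 0.347) and -0.26 with litter as a block. Epithelial marker genes, which are described further on, were highest on KO 1 and KO 2, and without those arrays the median was -0.27.

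Oxidative phosphorylation genes had a smaller shift. Of 44 measured members 43 had a negative log2 difference, with a median of -0.16 (camera adjusted p = 2.72e-15 with the preset correlation, adjusted p = 0.547 with an estimated correlation). No member passed adjusted over the list alone. Atp5o, a subunit of ATP synthase, differed by -0.28 and Sdhd, a membrane anchor of succinate dehydrogenase, by -0.36. The median was -0.11 within litter Cx34, -0.05 within litter Cx28 (adjusted p = 0.105), -0.08 with litter as a block and -0.18 without KO 1 and KO 2. The list mean had an exact permutation p of 0.0857 (adjusted p = 0.314).

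Markers of mature adipocytes were lower in KO, but not on all arrays alike. Of 29 measured members 24 had a negative log2 difference, with a median of -0.16 (camera adjusted p = 0.000144 with the preset correlation, adjusted p = 0.689 with an estimated correlation). Adjusted over the list alone 4 fell and 0 rose: Gpd1, which makes glycerol 3-phosphate for triglyceride, fell by 0.44, the lipid droplet protein Cidea by 1.62, the triglyceride-forming enzyme Dgat1 by 0.61, and Slc2a4, the insulin-responsive glucose transporter GLUT4, by 0.58. The 4 Gpd1 probe sets gave log2 differences from -0.65 to -0.04. Adipoq, chosen after its values were seen because it marks adipocytes, differed by -0.09 ± 0.07 (SE). The list mean was 10.92 on KO 2 and 11.19 on KO 1, against 11.32 on KO 3, 11.38 on KO 4 and a range of 11.35 to 11.48 over the LoxP arrays. Without KO 1 and KO 2, the arrays with the highest epithelial signal, the median was 0.00 and the call was lost (adjusted p = 0.458). Within litter Cx28 the median was 0.06 and within litter Cx34 it was -0.39, and with litter as a block it was -0.12.

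Thermogenic genes, which mark brown and beige fat, were also lower as a list. Of 19 measured members 15 had a negative log2 difference, with a median of -0.10 (camera adjusted p = 0.00444 with the preset correlation, adjusted p = 0.547 with an estimated correlation). Adjusted over the list alone 2 fell, Cox8b and Cidea, and 0 rose. Ucp1, the uncoupling protein of brown fat, chosen after its values were seen, read 6.37 ± 0.11 in KO and 6.35 ± 0.09 in LoxP (SD, n = 4 each), both under the background bound. Cidea was also in the mature adipocyte list, and its KO mean of 5.60 lay under that bound. The thermogenic median was -0.06 within litter Cx28, -0.16 within litter Cx34, where the call was lost, -0.08 with litter as a block and -0.10 without KO 1 and KO 2. Cox8b (-1.95) and Cidea (-1.62) weighed heavily in the list mean, which read 6.41 in KO and 6.67 in LoxP, both under the background bound. It differed by -0.25 with all arrays (exact permutation p = 0.0857, adjusted p = 0.314), larger in size than the median of -0.10. With litter as a block it differed by -0.29 (95% interval -0.66 to 0.09), and without KO 1 and KO 2 by -0.39 (-0.66 to -0.12).

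Genes of insulin signalling and glucose uptake had a median of -0.14 over 26 members, 20 of them negative (camera adjusted p = 0.0136 with the preset correlation, adjusted p = 0.547 with an estimated correlation). Besides Slc2a4, the glycogen synthase Gys1 (-0.51) and the phosphofructokinase Pfkl (-0.33) read lower and Akt1 (0.20, with another probe set at -0.10) read higher in KO, none past adjusted p over the list alone. This was the one list whose mean separated the groups, at 9.10 ± 0.06 in KO and 9.27 ± 0.02 in LoxP (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.314). Its median was 0.04 within litter Cx28, -0.24 within litter Cx34, -0.06 with litter as a block and -0.03 without KO 1 and KO 2, and the camera call was lost in each. The difference of the list mean was -0.17 with all arrays, -0.16 with litter as a block (95% interval -0.28 to -0.05) and -0.13 without KO 1 and KO 2 (-0.18 to -0.07). Because the list was picked for groups that did not overlap, these differences were bound to be negative and add no independent support. Fatty acid synthesis and esterification genes had a median of -0.18 over 25 members (camera adjusted p = 0.00547 with the preset correlation, adjusted p = 0.547 with an estimated correlation). There Mogat1 alone passed adjusted over the list, while Acaca, acetyl-CoA carboxylase 1, read -0.33 and the desaturase Fads1 0.58. That median was -0.25 within litter Cx28, -0.10 within litter Cx34 (adjusted p = 0.848) and -0.18 with litter as a block. Adipogenic transcription factors had a median of -0.15 over 25 members (camera adjusted p = 0.0211 with the preset correlation, adjusted p = 0.689 with an estimated correlation), with Stat5a at -0.36 and Egr2, whose LoxP mean lay under the background bound, at 1.60 ± 0.49 (SE), and no member passed adjusted over the list alone. This call was lost within litter Cx28, where the median was 0.14, with litter as a block (-0.07) and without KO 1 and KO 2 (0.02), while the median within litter Cx34 was -0.27.

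**Figure D3:**
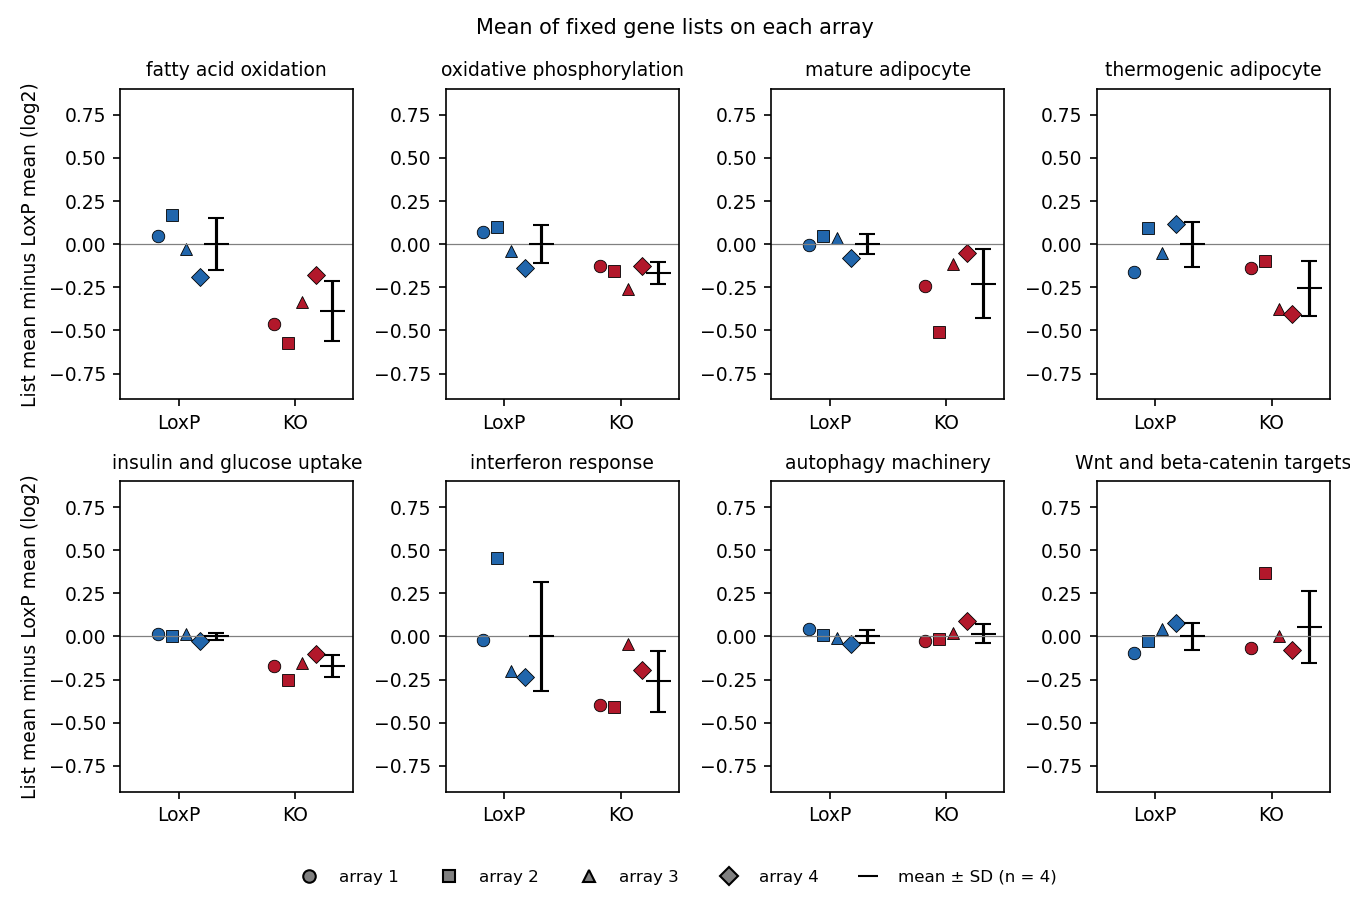
Mean of 8 fixed gene lists on each LoxP (blue) and KO (red) array, minus the LoxP mean (y axis, log2 units), with the mean ± SD of each group. Arrays 1 to 4 of a group are named by marker shape and are not paired. For insulin and glucose uptake all KO arrays lie below all LoxP arrays, and for autophagy machinery the groups overlap.

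Because TP53INP2 acts in autophagy and has been linked to beta-catenin signalling during adipogenesis, these lists were fixed for comparison. The autophagy machinery gave a median log2 difference of 0.01 over 34 members (camera adjusted p = 0.616, adjusted p = 0.910 with an estimated correlation), with 19 positive and 15 negative. Atg101, part of the ULK initiation complex, read -0.27 and Atg10, an E2-like conjugating enzyme, 0.23, and neither passed. The autophagy median was 0.08 within litter Cx28, -0.02 within litter Cx34 and 0.04 with litter as a block. Lysosomal genes had a median of 0.05 over 28 members (camera adjusted p = 0.0632, adjusted p = 0.689 with an estimated correlation). This list was called in 12 of 32 alternatives, among them without KO 1 and KO 2, where its median was 0.14 (adjusted p = 0.000521, adjusted p = 0.388 with an estimated correlation), and it read 0.05 within litter Cx28, -0.01 within litter Cx34 and 0.04 with litter as a block. Wnt and beta-catenin targets gave a median of 0.02 over 29 members (camera adjusted p = 0.604, adjusted p = 0.910 with an estimated correlation), with Cd44 at 0.61 (0.10 to 0.66 over its 4 probe sets) and Fosl1 at 0.24, neither past the test, and Fosl1 under the background bound. Their median was -0.13 within litter Cx28, 0.07 within litter Cx34 and 0.01 with litter as a block. The Wnt target list mean was 6.73 in KO and 6.68 in LoxP, under the background bound of 6.94, so differences of its dim members may be compressed. Wnt pathway components gave a median of 0.01 over 31 members (camera adjusted p = 0.671, adjusted p = 0.910 with an estimated correlation). Adjusted over that list alone 1 member fell, the non-canonical ligand Wnt5a, by 0.40 on the log2 scale, and 0 rose. Ryk, a receptor for Wnt ligands, read 0.26.

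The remaining 3 lists were called with the preset correlation. Interferon response genes were lower in KO, with a median of -0.24 and 25 of 28 members negative (camera adjusted p = 7.19e-05, adjusted p = 0.689 with an estimated correlation), Irf7 at -0.34 and Ifi27 at -0.30. The interferon median was 0.09 within litter Cx28, -0.21 within litter Cx34, -0.07 with litter as a block and -0.12 without KO 1 and KO 2 (adjusted p = 0.120), and the call was lost in each. LoxP 2 held the highest interferon list mean, 8.10, against 7.24 to 7.63 on the other arrays. Unfolded protein response genes were higher, with a median of 0.07 over 30 members (camera adjusted p = 0.0212, adjusted p = 0.547 with an estimated correlation), the secreted factor Manf at 0.56 and the asparagine synthetase Asns at -0.51. Immediate early genes, which also respond to handling of the animal, were higher with a median of 0.12 over 29 members (camera adjusted p = 0.00547, adjusted p = 0.668 with an estimated correlation), including Egr2 and Fosl2 at 0.23, whose other probe set gave 0.01. The last 2 lists lost their calls with litter as a block, where both medians were 0.08, and the unfolded protein response medians were 0.03 within litter Cx28 and 0.14 within litter Cx34. For immediate early genes they were 0.17 and -0.07. No member of these lists passed adjusted over its list alone.

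The other 19 lists were not called, with medians from -0.14 for blood to 0.30 for mural and smooth muscle cells and camera adjusted p from 0.0765 to 0.861 (adjusted p = 0.689 to 0.912 with an estimated correlation). They covered macrophages (0.03), T and NK cells (0.01), B and plasma cells (-0.01), granulocytes and mast cells (-0.03), endothelium (-0.08), adipose progenitors (0.05), extracellular matrix (0.02), mesothelium (-0.03), skeletal muscle (-0.02), inflammatory cytokines (-0.03), MHC class II (0.01), cell cycle (0.05), p53 targets (0.07), cholesterol synthesis (0.09), adipogenesis inhibitors (0.00), the circadian clock (-0.02) and epididymis and testis (0.05). The mean of the list differed in sign from the median for macrophages (-0.01), B and plasma cells (0.01), granulocytes and mast cells (0.04), mesothelium (0.09), skeletal muscle (0.06) and inflammatory cytokines (0.02). Without KO 1 and KO 2, 5 of the 19 were called with the preset correlation: macrophages (0.25, adjusted p = 0.000151), extracellular matrix (0.23, adjusted p = 0.000116), endothelium (0.17, adjusted p = 0.00421), p53 targets (0.16, adjusted p = 0.00366) and blood (-0.19, adjusted p = 0.00294), and 0 lists were called there with an estimated correlation. Cell cycle genes were called with litter as a block (0.07, adjusted p = 0.00312) and within litter Cx34 (0.12), and in 9 of 32 alternatives in all. Cholesterol synthesis genes were called in 10 of 32 alternatives, with medians of 0.22 within litter Cx34 and -0.19 within litter Cx28. Endothelial genes were called in opposite directions within litter Cx28 (0.27, adjusted p = 0.00467) and within litter Cx34 (-0.50, adjusted p = 6.31e-08). With an estimated correlation 0 lists were called with litter as a block or within either litter, where cell cycle genes had adjusted p = 0.839 with the block and 0.946 within litter Cx34, and endothelial genes 0.944 within litter Cx28 and 0.927 within litter Cx34. Adjusted over the list alone, Trp63 rose within the p53 list and no member of the other 18 passed. The endothelial nitric oxide synthase Nos3 read -0.68 and the chemokine Ccl8 -0.74, and neither passed. List means under the background bound in both groups were those of T and NK cells, B and plasma cells, and granulocytes and mast cells. Those of cell cycle, skeletal muscle, and epididymis and testis lay there too. The lack of a call for these lists is therefore less informative.

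Transcripts of the male reproductive tract stood far above the LoxP level on some arrays. Spink8, an epididymal protease inhibitor, read 12.33 on KO 1, 11.86 on KO 2 and 9.30 on KO 3, against 5.49 on KO 4 and 5.40 ± 0.08 (SD, n = 4) in LoxP, and the group difference did not pass (limma adjusted p = 0.633). Of 34 epididymis and testis genes measured, 7 on KO 1, 4 on KO 3, 2 on LoxP 4 and 1 on KO 2 were over 4-fold above the LoxP median, and 0 were on KO 4, LoxP 1, LoxP 2 and LoxP 3. The genes on LoxP 4 were Lcn2, which is also in the inflammatory cytokine list, and Cuzd1, while Spink8 read 5.34 there. A list of epithelial markers written after these values were seen averaged 8.28 on KO 1 and 8.72 on KO 2, 7.37 on LoxP 4, and between 5.60 and 6.29 on the other arrays. Mural and smooth muscle genes averaged 10.06 on KO 2 and between 8.41 and 8.86 elsewhere. A list of ciliated cell genes, also not among the fixed lists, averaged 6.72 on LoxP 4 and between 5.35 and 5.70 elsewhere. The first principal component held 45.1% of the variance and set KO 2 and KO 1 apart from the rest, and its leading gene was the epididymal serpin Serpina1f, chosen after its values were seen. With KO 1 and KO 2 left out, limma called 0 genes and 1285 had an unadjusted p under 0.05.

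**Figure D4:**
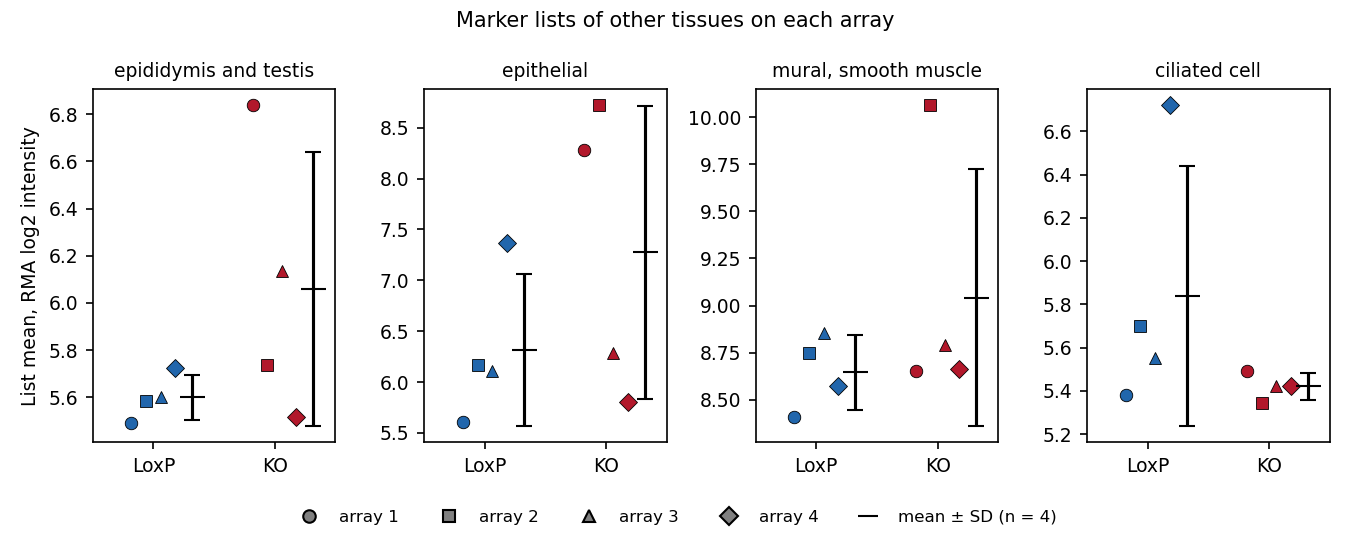
Mean RMA log2 intensity (y axis) of marker lists of other tissues on each LoxP (blue) and KO (red) array, with the mean ± SD of each group. KO 1 and KO 2 lie highest for epithelial genes, KO 2 for smooth muscle genes and LoxP 4 for ciliated cell genes, and the y axes do not start at 0.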

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

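The tests weighed here were chosen after the results were seen, except the splits of the arrays for the adjusted count. The test of the ciliated cell list was set before its list mean was read, but after LoxP 4 was seen to lie apart. The bounds for dilution and litter in the fatty acid oxidation and mature adipocyte lists were changed to a 95% interval, and the bound for a deletion effect on epithelial genes to the highest of LoxP 1, LoxP 2 and LoxP 3, once the values were known. Among 172 groups of 4 readings checked for a reading far from the other 3, 9 held one, and chance gives about 1 in 20. The gap to the nearest reading, as a share of the range, was 0.866 for Tmem45b (KO 4 lowest), 0.886 for Acaa1b (KO 2 lowest), 0.899 for Fosl1 (KO 4 highest), 0.882 for Nos3 (KO 2 lowest) and 0.877 for Ifi27 (LoxP 2 highest). Among list means it was 0.905 for mural and smooth muscle and 0.883 for skeletal muscle, both with KO 2 highest, 0.935 for blood with KO 1 highest, and 0.883 for MHC class II with KO 3 highest. The KO effect differed between litters Cx28 and Cx34 for 8 genes by an interaction test (limma, adjusted p under 0.05), among them Cdh1. In all 8 the highest reading was on KO 1, KO 2 or LoxP 4.

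The first pattern is the signal of male tract genes, where epithelial markers averaged at least 8.28 on KO 1 and KO 2, above every other array, which is consistent with epididymal or adjoining tissue having been taken with the fat pad, though the marker list was written after leading genes of the pattern were seen. An effect of the deletion on adipose cells stays open: KO 3 and KO 4 together lay -0.26 from the LoxP mean, but LoxP 4 (7.37) raises that mean, and KO 3 (6.29) lay above LoxP 1, LoxP 2 and LoxP 3 (5.60 to 6.17). KO 4 (5.81) lay within that range, although its Trp53inp2 reading was lowered to 10.88. The signal was thus low on a KO array and raised on a LoxP array, so it did not follow genotype on every array. Each of these readings rests on a single mouse. On LoxP 4 the ciliated cell list lay 1.02 above the next highest LoxP array, so ciliated tissue of the tract is a candidate source there, with Tmem212 at 9.41 and Ak7 at 9.08. The bound of 1 was set before the list mean was read, and it was passed narrowly. But the list was not among the fixed lists. It was scored for a pattern already seen, LoxP 4 lying apart on the third principal component, whose leading gene was Tmem212. A high value on LoxP 4 was therefore likely in advance and adds little independent support. Of the measured markers, 2 of 24 ciliated and 2 of 25 epithelial genes exceeded the background bound on all LoxP arrays, and 3 of the epithelial genes were also in fixed lists.

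The second pattern is the lower reading of fatty acid oxidation and mature adipocyte genes in KO. Tract tissue could have diluted the adipocyte transcripts: without KO 1 and KO 2 the mature adipocyte list mean differed by -0.083 (95% interval -0.21 to 0.05) in place of -0.23, and the fatty acid oxidation mean by -0.25 (-0.59 to 0.08) in place of -0.39, or by -0.28 (-0.63 to 0.07) with litter as a block. Against dilution, the fatty acid oxidation median stayed at -0.34 with the epididymis list mean as a covariate. But the list mean with that covariate was -0.33 (-0.68 to 0.03), and the covariate read KO 2 (5.74) much like LoxP 4 (5.72). For KO 4 alone the median was -0.20, smaller in size than the -0.37 with all arrays. The list mean of KO 4 (10.02) lay just above that of LoxP 4 (10.01), whose epithelial list mean was raised (7.37). It lay below those of LoxP 1, LoxP 2 and LoxP 3 (10.17 to 10.37). KO 4 is a single mouse, so it does not decide the question. With LoxP 4 left out besides KO 1 and KO 2, the fatty acid oxidation median was -0.35, close to the -0.37 with all arrays. It was -0.27 with LoxP 4 kept, so that smaller median depended on LoxP 4. This goes against dilution for fatty acid oxidation, but the mature adipocyte median in the same run was -0.016. Dilution, litter and genotype cannot be told apart here, because only 2 KO arrays remain and each shared litter holds 1 LoxP array. Chance could not be excluded either: 2 of the 35 splits of the arrays, counting the real one, gave a fatty acid oxidation median as large in size as the real 0.37, and the highest other split gave 0.41. That other split set KO 1, KO 2, KO 3 and LoxP 4 against the rest. These are the arrays with genes of the epididymis list over 4-fold above the LoxP median, but they do not share the same genes. On LoxP 4 the genes were Lcn2 (11.35) and Cuzd1 (10.63), while Spink8 (5.34) and Adam7 (4.41) stayed at the LoxP level. The shift was thus at least as large along that grouping of arrays as along genotype, which does not tie it to a single epididymal signal.

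The third pattern is Apoc1, which was lower in KO with a log2 difference of -1.61. Without KO 1 and KO 2 the log2 difference was -1.63 ± 0.19 (SE). It was -1.42 ± 0.13 with litter as a block, -1.27 ± 0.18 within litter Cx28 and -1.57 ± 0.18 within litter Cx34. All KO readings (9.61 to 9.97) lay below all LoxP readings (11.05 to 11.64), so these differences were bound to be negative. Their sign therefore weighs little against dilution by tract tissue or against litter, but their size was not bound. Without KO 1 and KO 2 the mature adipocyte list mean differed by only -0.083, against -1.63 for Apoc1. KO 2, which had the highest epithelial list mean, held the highest Apoc1 reading of the KO arrays (9.97). These values argue against dilution of adipocytes as the whole of the Apoc1 difference. Litter stays open, because each shared litter holds 1 LoxP array. KO 4, with 0 epididymal genes over 4-fold above the LoxP median, read 9.95, so the low reading was not confined to arrays with that signal. It also stays open that genotype and Cre activity differed together, that the gene was picked as the smallest p of 17097, and that its adjusted p ran from 0.0163 to 0.999 over the alternatives. That the deletion lowers Apoc1 is therefore a hypothesis.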

How the results depend on the processing

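Trp53inp2 was lower in KO in each alternative, with log2 differences from -0.76 to -1.81, and its unadjusted p passed 0.05 in all but litter Cx28 alone (-0.76). The cause of the changes below was not tested. Leaving out KO 1 and KO 2, KO 1, KO 2 and LoxP 4, all KO arrays but KO 4, and the covariate were chosen after seeing the data. No paired analysis was possible because the replicate numbers are accession order and the labels match mice by litter only, which was fitted as a block. Rescaling moved the median of all genes by at most 0.0129. Signs turned within litter Cx28 for Asns (0.11) and Atg10 (-0.016), and in 4 alternatives for Trp53inp1 (-0.034 to -0.0093). The signal over background limits Trpv1, Cpm, Lama3, Fosl1, Ucp1 and the KO readings of Cidea, Arxes1 and Aatk, and the LoxP readings of Egr2, Trp63, Arhgap11a and Spink8.

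Genes lower in KO numbered 1 at adjusted p under 0.10, with array weights, with genes under the 40th or 60th percentile left out, within litter Cx34 and, among arrays left out in turn (range 0 to 1), without LoxP 4. They numbered 2 with the probe set of largest variance (Apoc1 and Gpd1) and 95 within litter Cx28. Apoc1 passed 0.05 in 5 alternatives and passed the looser 0.10, and within litter Cx28 Cox8b did. Genes higher numbered 6 within litter Cx34. Genes at an unadjusted p under 0.05 numbered 3036 of 45037 over all probe sets, 745 with the covariate, 680 above the 60th percentile, 650 for KO 4 alone, 698 without litter Cx33, and 776 to 1639 with 1 array left out, lowest without LoxP 2.

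Lists called higher (2 in the report) numbered 8 without KO 1, KO 2 and LoxP 4, 7 at adjusted p under 0.10, 7 with array weights, 7 without KO 1 and KO 2, 9 over all probe sets, 5 for KO 4 alone, 4 with the probe set of largest variance, 1 above the 60th percentile, 1 with litter as a block (cell cycle), 1 without litter Cx33, 0 with an estimated correlation, 0 with directional fry, and 0 to 5 with 1 array left out (0 without LoxP 1, 1 without LoxP 3, 5 without KO 1, KO 2, KO 4 or LoxP 4). Lists called lower (8) numbered 5 with litter as a block, without litter Cx33, without KO 1 and KO 2, and without KO 1, KO 2 and LoxP 4, 2 within litter Cx28, and 0 with an estimated correlation or fry.

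Calls were lost for mature adipocyte genes without KO 1 and KO 2 (median 0.0013), without these and LoxP 4 (-0.016) and for KO 4 alone (0.028), and the median turned to 0.057 within litter Cx28. Within that litter fatty acid oxidation (-0.039) and oxidative phosphorylation (-0.052) lost theirs, as did thermogenic genes above the 60th percentile (-0.17) and within litter Cx34 (-0.16). With an estimated correlation fatty acid oxidation (-0.37), mature adipocyte (-0.16), oxidative phosphorylation (-0.16) and thermogenic (-0.10) genes lost theirs. Autophagy genes were called for KO 4 alone (0.088, 1 array against 4) with the preset but not with an estimated correlation (adjusted p = 0.756), read -0.019 within litter Cx34, and ran from -0.012 (without KO 4) to 0.037 with 1 array left out. Wnt targets were called over all probe sets (0.024) and read -0.13 within litter Cx28, -0.037 for KO 4 alone, -0.034 without KO 1 and KO 2, 0.0075 without these and LoxP 4, -0.0049 with array weights, 0.0076 with litter as a block or without litter Cx33, and -0.020 (without KO 2) to 0.039 with 1 array left out.

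Directions turned within litter Cx28 for adipogenic transcription factors (0.14), endothelium (0.27) and interferon response (0.088), and within litter Cx34 for MHC class II (-0.19), extracellular matrix (-0.16) and immediate early genes (-0.071). They also turned for endothelium without KO 1 and KO 2 (0.17), T and NK cells for KO 4 alone (-0.050), and macrophages, which ran from -0.12 (without KO 3) to 0.11 with 1 array left out. The cholesterol synthesis median turned within litter Cx28 (-0.19), with the covariate alone (-0.033) or with litter block (-0.049), and for KO 4 alone (-0.015).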

Other observations

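The tests below were chosen after the results were seen, except the splits for the adjusted count. The transcripts raised on single arrays differed between arrays. KO 1 held 63 genes over 4-fold above every other array, among them the epididymal genes Defb2 (10.64) and Crisp4 (9.64). KO 2 held 93, among them Ptgs2 (11.59), Pcp4 (12.52) and the smooth muscle genes Actg2 (11.76) and Cnn1 (12.44), together with the posterior patterning gene Hoxa10 (8.97) and the striated muscle genes Tnnc2 (11.43) and Casq1 (10.02). LoxP 4 held 34, among them the metabolic gene Fbp1 (8.38) and the cilium gene Fam183b (8.51). KO 3, KO 4, LoxP 1 and LoxP 2 held 0 and LoxP 3 held 2, both immunoglobulin genes. These genes were chosen after their values were seen.

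Within litter Cx28 alone, limma called 95 genes lower in KO. For 91 of them LoxP 4 held the highest of the 8 readings, and 6 were in the ciliated cell list. Within litter Cx34, 7 genes were called, among them the epithelial genes Cdh1 and Cldn1, and 0 genes were shared between the litters.

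The next 3 genes were chosen after their values were seen. Pparg read 11.09 ± 0.31 in KO and 11.29 ± 0.15 in LoxP, and Cebpa read 12.23 ± 0.19 and 12.38 ± 0.04 (SD, n = 4 each), with KO 2 lowest for both. Ctnnb1, which encodes beta-catenin, read 11.76 ± 0.04 in KO and 11.72 ± 0.04 in LoxP.

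Other splits of the 8 arrays into 4 and 4 gave results as large as the real one, and the counts of splits below include it. For genes past the adjusted threshold the real count was 0 and the highest of the other splits gave 1, so all 35 splits gave at least as many by construction and the comparison decides nothing about chance. At an unadjusted p under 0.05 the real count was 1250 and the highest other split gave 2302, with 5 of the 35 splits as large, so chance cannot be excluded. Each of the other splits that large put KO 1, KO 2 and LoxP 4, the arrays with the highest epithelial list means, on the same side. Those splits therefore follow that signal, and the comparison does not measure chance alone. That highest split set KO 1, KO 2, KO 3 and LoxP 4 against the rest. These are the 4 arrays with genes of the epididymis list over 4-fold above the LoxP median, though not the same genes on each. The split differs from the real one by the exchange of KO 4 and LoxP 4 and gave 0 genes past the adjusted threshold. For lists called by camera the real count was 10 and the highest other 18, with 13 of the 35 splits as large, so the preset correlation alone does not separate these calls from chance.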
